A study of Mus musculus with 2 samples.

How the data were processed

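ATAC-seq, which uses the Tn5 transposase to cut and tag accessible chromatin, was performed on GFP-positive cells sorted by FACS from Hb9::GFP mouse embryos of the C57/Bl6 strain at embryonic day 10.5. Hb9 is an older name of Mnx1, a homeobox gene of motor neurons, and the labels call the sorted cells motor neurons. The identity of the cells was not tested separately. The labels give 1 group of 2 replicates, with 8 to 9 PCR cycles per library and paired 75-nt reads. They do not say whether the replicates came from separate litters.

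The data analysed here were 1 pooled, filtered peak list for both replicates, so no value has a replicate error and no replicate could be left out. The submitters' processing notes name Trim Galore, cutadapt 0.6.2, BWA 0.7.1.7, SAMtools 1.7.2, MACS2 2.2.7.1 and the mm10 build. Their roles, settings, the handling of duplicate reads, any shift of reads for the Tn5 cut and the filter that was applied are not given in the sources used here. Each deposited entry holds an interval, a summit, a score, a fold and 2 significance values. The fold is a ratio of the reads at the summit to the caller's local background, as deposited by the authors. The significance values are the −log10 of the caller's p-value and q-value, as deposited by the authors. The deposited score equals 10 times the −log10 p, cut to a whole number, in 99.999% of entries, and was not used further. Fold and significance are the authors' values throughout.

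The depth behind each entry was recovered from the deposited fold and −log10 p. A background and a read pileup were solved from the Poisson tail above the pileup and the ratio (pileup + 1)/(background + 1). The pileup came out within 0.01 of a whole number in 99.96% of entries, although nothing in the solution requires it. These pileups are called reads below. They are overlapping reads or fragments at 1 base, and the total depth of either library is not known. The smallest pileup was 11 reads and the genome-wide background was 5.37 reads. A site without an entry is therefore below the caller's limit, not shown to be closed. Pileups carry counting error. The exact binomial interval treats entries as independent, although up to 20 of them share 1 peak interval. The bootstrap interval covers the spread between genes. Neither covers replicate error.

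Genes were taken from a table of the GRCm38.p6 assembly, the assembly behind mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. This table gives gene starts and ends but no strand, exon, transcript start or sequence. The planned windows around transcription start sites were therefore replaced by windows of 1 kb to either side of both gene ends. Gene spans can reach past the main promoter, which then lies inside the span. The planned matching on promoter CpG content was replaced by matching on gene length, and the planned motif search and exon classes were not run. Distal entries had a summit more than 1 kb from every gene end and were assigned to the gene with the nearest end within 100 kb. The territory of a gene is the sequence nearest to its ends within that reach. Coordinates are mm10, counted from 1.

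Before the data were examined, 23 gene lists were fixed, holding 335 different genes, all of which matched a symbol. They covered motor neurons, neurons in general, progenitors, other cell types that a sort or embryo could hold, housekeeping genes and the Hox clusters. Each list was compared with 10000 random lists of the same size, drawn from genes of the same of 10 equal classes of gene length (gene ends) or territory length (distal entries). A list was called high in the top 2.5% of random lists and low in the bottom 2.5%. By chance about 5% of lists pass these limits. The motor neuron transcription factor list was compared with 13 lists of other cell types by reassigning the genes of both lists 10000 times. These percentiles describe this peak list, and genes are not replicates, so no p-value is given. Shares of entries were compared with 100 random placements of the entries within their chromosomes. Assembly gaps could not be left out of the placements.

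The genes named were fixed by rule before the data were examined. They are all members of the motor neuron transcription factor and cholinergic lists, and all Hox genes. From each other list came the 3 members with most distal entries and up to 2 without a gene-end entry. Genome-wide, the 10 genes with most distal entries and the 10 chromosomal entries with the highest −log10 q were taken. Not every gene the rule selects is named individually, and genes named outside it are marked as such. The scripts were tested on simulated data. All 5000 simulated pileups were recovered to within 0.01 read (100.0%). With entries placed at random, 2 of the 23 lists passed a limit for distal entries and 1 of the 13 comparisons of lists did. With a 3-fold excess planted at the motor neuron transcription factors, that list reached the 100.0th percentile and all 13 comparisons passed. Alternatives varied the entries used, the window, the reach, the overlap rule and the matching. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.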

Results

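Accessible chromatin of sorted cells labelled as motor neurons at embryonic day 10.5 was described from 138387 summit entries in 104069 separate intervals, pooled over 2 replicates. The intervals covered 52.7 Mb and had a median width of 379 bp. The median entry rested on 24 reads at its summit, and 90% of entries lay between 12 and 129 reads. The list was permissive: the smallest −log10 p was 2.0, and 24503 entries (17.7%) had a q-value of 0.05 or more. A single group was profiled, without a comparison tissue or control, so the questions that can be asked are where the entries lie and beside which genes they gather. Neither replicate error nor a test between conditions exists for any value below.

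Accessible sites were concentrated at the ends of protein-coding genes. Of 137849 entries on the chromosomes, 18.3% had their summit within 1 kb of a gene end (95% exact binomial interval 18.1 to 18.6%), against 3.09% of randomly placed entries (range 2.95 to 3.20% over 100 placements), a 5.94-fold excess. Entries inside genes made up 40.0%, close to the 38.6% of random placements, and those between genes 41.6% against 58.3%. Entries at gene ends were also stronger, with a median of 5.49-fold enrichment and 64 reads, compared with 2.98-fold and 21 reads elsewhere. In all, 14688 genes (67.1%) had an entry within 1 kb of an end, and the highest such entry of a gene had a median of 8.22-fold. Of the housekeeping genes, which are active in most cells, 22 of 23 had a gene-end entry (99.9th percentile). The median among them was 7.48-fold, below the 8.22-fold of all genes with one. Fold divides by the local background, so a lower fold need not mean fewer reads. Housekeeping genes had a median of 1 distal entry, which equalled that of matched random lists. Ywhaz was the exception at its ends, and its strongest entry (7.36-fold, 169 reads) lay inside the gene, 9295 bp from the nearer end.

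The motor neuron transcription factors, a list of homeobox and other regulators, had a gene-end entry at 14 of 15 genes. Membership of the list does not mean that a gene acts only in motor neurons. The median of the list, 6.12-fold, was below the 8.22-fold of all genes with one, which only Isl1 and Ebf1 exceeded. The local background at these entries ran from 5.37 reads (Ebf1) to 53.9 (Mnx1), so a lower fold need not mean fewer reads. Reads ran from 37 (Myt1l) to 406 (Mnx1), against a median of 99 at autosomal gene ends with an entry. The strongest gene-end entry of the list belonged to Isl1, a LIM homeobox factor that directs motor neuron identity. It lay at chromosome 13, 116309386 to 116310253, with 10.9-fold enrichment and 244 reads. Ebf1 followed with 9.27-fold, then Mnx1 with 7.42-fold, Nkx6-1 with 7.24-fold, Ebf2 with 7.14-fold and Onecut2 with 6.96-fold. The entry of Ebf1 lay at its higher-coordinate end, with 58 reads over a background of 5.37. No strand was used, so any of these entries may lie at the start or at the far end of its gene. Lhx3, the LIM homeobox partner of Isl1, had the lowest value of the list at 4.01-fold and 38 reads (chromosome 2, 26207537 to 26208576). Between these lay Zeb2 at 6.12-fold, Onecut1 at 6.11-fold, Nkx6-2 at 6.09-fold, Lhx4 at 4.78-fold, Ebf3 at 4.75-fold, Onecut3 at 4.72-fold and Myt1l at 4.27-fold. Isl2 had no entry within 1 kb of its annotated ends. Its strongest entry, 7.096-fold with 120 reads, lay inside the gene at chromosome 9, 55540661 to 55541285, 2364 bp from the nearer end. The list's share of 93.3% stood at the 96.0th percentile of random lists matched on gene length, below the limit for a call. It passed the limit under 3 of 8 alternatives: 98.3 with the upper 50% of entries by −log10 q, 97.7 with a 500 bp window and 98.9 without matching. The other 5 stayed below it, lowest at 86.2 without entries of a background of 30 reads or more, the setting that removes the Mnx1 entry, and 93.1 against named genes.

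Genes of cholinergic transmission and related motor neuron products had a gene-end entry at 6 of 8 members, a share at the 64.6th percentile. Slc5a7, the choline transporter, reached 9.90-fold and Slc10a4 8.15-fold. Calca, which encodes calcitonin and CGRP, reached 6.62-fold, and Ache, acetylcholinesterase, 6.38-fold. Chat, which makes acetylcholine, and Slc18a3, which loads it into vesicles, share a locus and 1 entry of 5.10-fold and 57 reads at chromosome 14, 32464156 to 32465422. Prph (peripherin) and Calcb had none at their ends, but entries of 4.68-fold and 3.61-fold inside the genes. The motor column and subtype genes had one at 10 of 12 members (63.0th percentile), with Nos1 and Runx1 as the exceptions.

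Distal sites gathered strongly around the motor neuron transcription factors. These 15 genes held 326 distal entries, with a median of 17 per gene, more than any of the 10000 random lists matched on territory length (central 95% of 2 to 9). Zeb2 had 53, Ebf2 44, Ebf3 43, Ebf1 29, Lhx4 22 and Nkx6-2 21. Onecut1 had 19, Nkx6-1 17, Myt1l 15, Isl1 14, Lhx3 13, Onecut2 12, Onecut3 11, Mnx1 8 and Isl2 5. Zeb2 and the Ebf genes thus led the counts, and Isl1, Lhx3, Mnx1 and Isl2 were among the members below the median of 17. Per 100 kb of territory, Lhx3 (33.9) and Lhx4 (30.5) had the most of the list. The excess belongs to the list as a whole and was not tested for any narrower set of its members. Among the strongest distal entries was 1 of 10.9-fold beside Ebf2, between genes at chromosome 14, 67506833 to 67507587 and 76.2 kb from the gene. The strongest around Nkx6-1 had 7.97-fold (chromosome 5, 101590464 to 101591712, between genes, 68.5 kb away). For Onecut1 it had 8.58-fold (chromosome 9, 74846688 to 74847857, between genes, 14.9 kb away). Around Lhx3 the highest was 5.94-fold (chromosome 2, 26175132 to 26175839, between genes, 24.9 kb away), and around Isl1 5.97-fold at 96.8 kb.

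The other motor neuron and neuronal lists were high as well. Motor column and subtype genes had a median of 13 distal entries (99.1st percentile), led by Tshz1 with 34, Foxp1 with 33, the cofactor of Hox proteins in limb-level motor neurons, and Bnc2 with 23. With a reach of 50 kb this list fell to the 96.2nd percentile. Cholinergic genes had a median of 5.5 (99.7th percentile). Prph had 7, Chat, Slc18a3 and Slc5a7 6 each, Slc10a4 5, Ache and Calcb 4 each and Calca 2. The cholinergic call was lost with the upper 50% of entries (97.3), without matching (96.6) and with 1 entry per interval (96.5). The strongest of these around Chat had 5.97-fold (chromosome 14, 32428741 to 32429657) and that assigned to Slc18a3 7.54-fold (32437243 to 32437928), both inside Chat. Axon guidance and adhesion genes had a gene-end entry at 20 of 20 members and a median of 19.5 distal entries, above every random list. Its gene-end share stood at the 99.4th percentile, and the call was lost with the upper 50% of entries (92.5). Over whole gene spans it stood at 84.5, the most that 20 of 20 members could reach there, because tied random lists count only in part. Epha4, a receptor that sorts motor axons in the limb, had 48, and the semaphorin receptors Nrp2 and Nrp1 had 43 and 37. Pan-neuronal genes had a gene-end entry at 20 of 21 members and a median of 13 distal entries, also above every random list. Elavl4, an RNA-binding protein of neurons, had 13.3-fold at its end and 36 distal entries, Ncam1 34 and Syt1, the synaptic calcium sensor, 29. Mapt had none at its ends and an 8.21-fold entry inside the gene.

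**Figure D1:**
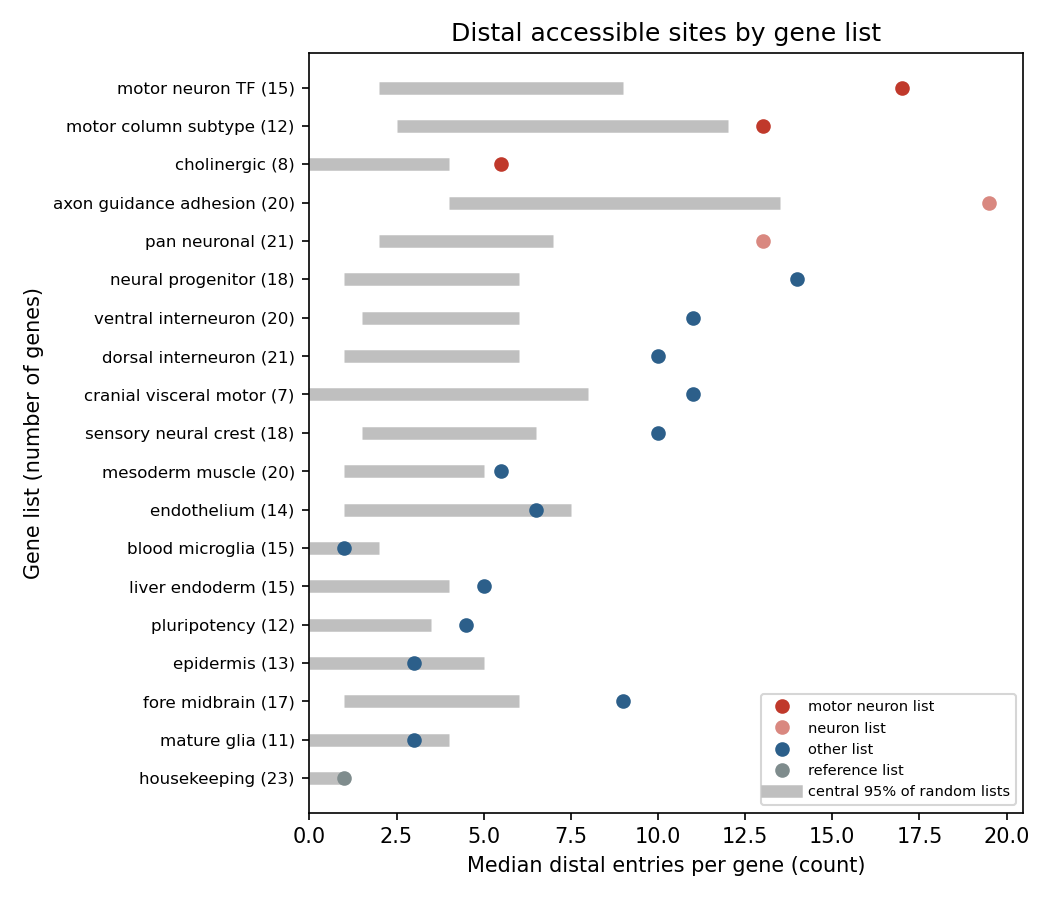
Median number of distal entries per gene (horizontal axis, count) for 19 gene lists (vertical axis, number of genes in brackets). Points are the lists, coloured by class, and grey bars are the central 95% of 10000 random lists matched on territory length; the motor neuron transcription factors lie at 17 against a bar from 2 to 9, and housekeeping genes at 1.

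Genes of other neural cell types were accessible too. All 18 neural progenitor genes had a gene-end entry, and their median of 14 distal entries was above every random list. Pax6 had 35, Sox2 30 and Sox1 29. Ventral interneuron genes had a gene-end entry at 19 of 20 members and a median of 11 distal entries, with 47 at Pax2, 19 at Sim1 and 18 at Gata3. Dorsal interneuron genes had one at 20 of 21 members and a median of 10, with 31 at Lmx1b, 29 at Olig3 and 20 at Lhx2. Sensory neuron and neural crest genes had one at 16 of 18 members and a median of 10, with 23 at Ntrk3, 21 at Tfap2b and 19 at Eya2. Genes of the forebrain and midbrain had one at 16 of 17 members and a median of 9, with 18 at Otx2, 16 at Nkx2-1 and 14 at Dlx2. The call of that list for distal entries was lost when sites within 5 kb of a gene end were left out (79.2nd percentile). The cranial and visceral motor list had one at 7 of 7 members and a median of 11, with 21 at Hand2. All 6 of these lists were high for distal entries (99.7th percentile or above), although the cranial and visceral list fell to 94.7 without sites within 5 kb. For gene ends 5 were high. The cranial and visceral list stood at 96.7, the most that 7 of 7 members could reach, because tied random lists count only in part. A call was therefore not possible for it at this setting. The gene-end call was lost with the upper 50% of entries for ventral interneurons (82.5), forebrain and midbrain (97.4) and sensory neurons and neural crest (96.2). The last was also lost with a 500 bp window (95.3) and against named genes (92.3), and the cranial and visceral list became high with the 500 bp window (97.9).

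Lists of non-neural cells and of mature glia varied. Blood and microglia genes had a gene-end entry at 4 of 15 members, the only list called low (0.56th percentile), and a median of 1 distal entry (57.2nd percentile). Alas2 and C1qa were among the members without a gene-end entry. Spi1, a myeloid regulator, had 11.0-fold and 128 reads at its end, and Ptprc had 16 distal entries. Endothelial genes had one at 8 of 14 members (15.1st percentile) and a median of 6.5 distal entries (94.3rd), with 17 at Flt1. The endothelial list became high for distal entries under 4 of 8 alternatives, at 98.5 with a reach of 50 kb, 99.8 without matching, 98.1 without sites within 5 kb and 97.8 with 1 entry per interval. Epidermal genes had one at 9 of 13 (38.7th percentile) and a median of 3 distal entries (75.9th), with none at all for Krt14. Mature glial genes had one at 6 of 11 (7.38th percentile) and a median of 3 (89.9th); Aqp4 and Gfap had none at their ends and Mbp had 21 distal entries. This list became low at gene ends with the upper 50% of entries (1.28) and high for distal entries without sites within 5 kb (98.5). Mesoderm and muscle genes (16 of 20, median 5.5), liver and endoderm genes (10 of 15, median 5) and pluripotency genes (7 of 12, median 4.5) were high for distal entries, at the 98.3rd, 99.5th and 99.3rd percentiles, but not for gene ends. Over whole gene spans in place of gene ends, endothelial genes stood at 92.5, mature glia at 91.2, pluripotency genes at 93.4, liver and endoderm at 98.8, mesoderm and muscle at 99.1, and blood and microglia at 0.18. The distal pluripotency call was lost with the upper 50% of entries (75.3rd percentile), without matching (96.3) and with q-values under 0.05 (97.1). The distal liver call was lost without sites within 5 kb (97.48), and the distal mesoderm call under 4 alternatives, lowest without sites within 5 kb (85.7th).

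The motor neuron transcription factors had more distal entries per 100 kb of territory than most lists of other cell types. Their mean per gene was 16.6. It exceeded blood and microglia genes (3.54), epidermis (4.27), mesoderm and muscle (7.43), pluripotency (7.49), mature glia (8.34), sensory neurons and neural crest (8.54), liver and endoderm (8.91), endothelium (9.14), forebrain and midbrain (10.7) and ventral interneurons (11.4). These 10 of 13 differences lay in the top 2.5% of reassigned lists. The differences to dorsal interneurons (11.99, 96.2nd percentile) and to cranial and visceral motor genes (10.9, 93.1st) did not reach it. Neural progenitor genes had 17.1, and the difference of −0.50 lay well within the −5.98 to 6.01 of reassigned lists. These means weight each gene equally, whatever its territory, and the reassignment was not matched on territory length. Pooled over territory, the motor neuron transcription factors had 13.4 entries per 100 kb. Ventral interneuron genes then had 11.0, dorsal interneuron genes 11.6 and neural progenitor genes 14.8. With the upper 50% of entries the call was lost for ventral interneurons (94.3), liver and endoderm (93.5) and endothelium (97.4), and gained for dorsal interneurons (99.7). With q-values under 0.05 it was also lost for ventral interneurons (97.3) and gained for dorsal interneurons (98.7), and without sites within 5 kb it was gained for cranial and visceral motor genes (98.6). For forebrain and midbrain it was lost with q-values under 0.05 (96.6), with a reach of 50 kb (97.45) and without high-background entries (97.46).

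Hox genes, which assign motor neurons to levels of the spinal cord, had a gene-end entry at 37 of 39 genes, with Hoxd10 and Hoxd11 as the exceptions. These 2 had entries of 5.52-fold and 4.43-fold inside their spans. The gene-end share was high for Hoxa (99.75th percentile), Hoxb (99.55th) and Hoxc (99.1st), but not for Hoxd (7 of 9 genes, 80.8th). The median number of distal entries was above every random list for Hoxa and Hoxb and high for Hoxc (97.8th percentile), but not for Hoxd (94.8th). Entries numbered 0.512 per kb over Hoxa (chromosome 6, 52155367 to 52260880), against 0.0512 per kb over all chromosomes. Over Hoxd (chromosome 2, 74668225 to 74765142) there were 0.454 per kb and over Hoxb (chromosome 11, 96194316 to 96368254) 0.374. Hoxc (chromosome 15, 102921131 to 103036856) had 0.337, the lowest of the 4 and 6.59 times the density over all chromosomes. The 4 genes of paralog group 13, the most caudal, had 5.50 to 7.77-fold with 37 to 78 reads, over a background of 5.91 to 9.17 reads. The background at groups 1 to 9 was 11.7 to 29.0 reads, so the fold of group 13 did not come with the most reads. Hoxa4 had 117 reads at 5.58-fold and Hoxc5 104 at 4.50-fold. Hoxd1 had the highest value at 9.07-fold and 136 reads, and Hoxb6 the lowest entry at 1.62-fold. Neighbouring genes can share 1 entry, as Hoxa10 and Hoxa11 did. The random lists drew genes from across the genome and left out this dependence, so the Hox percentiles may be overstated. With the upper 50% of entries, 76.9% of Hox genes kept one, against 94.9%.

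**Figure D2:**
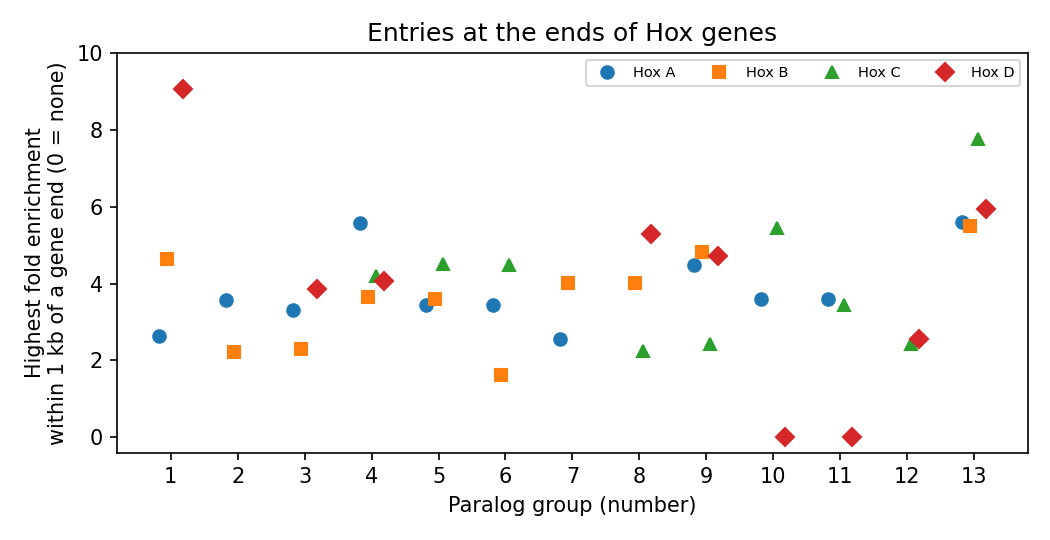
Highest fold enrichment of an entry within 1 kb of either gene end (vertical axis, ratio) for the 39 Hox genes, by paralog group (horizontal axis) and cluster (symbols). Points at 0 are Hoxd10 and Hoxd11, which had none; group 13 lies between 5.50 and 7.77.

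Among all genes, the most distal entries lay around Meis1 (65) and Meis2 (56), homeobox cofactors of Hox proteins, and around Dach1 and Zfp608 (56 each). Adgrl2 had 55, and Zeb2, Zfp516 and Fto 53 each. Zswim6 and the predicted gene Gm52481 had 52 each. The territory of Gm52481, on the Y chromosome, held entries with a background of up to 66.4 reads. The 10 entries with the highest −log10 q lay in 6 intervals, of which none was within 20 kb of a gene end. The highest, at chromosome 2, 98666253 to 98667321, had 12165 reads at a background of 829 reads. Of the others, 4 lay in 1 interval on chromosome 1, 24611609 to 24616113, where the background was about 3050 reads and the fold only 3.13 to 3.32.

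The Hb9::GFP transgene is known to carry about 9 kb of sequence upstream of Mnx1, so the entries beside the gene were examined on their own. Within 9 kb of the higher-coordinate end of Mnx1 (chromosome 5, 29478471 to 29487470) there were 7 entries, with a median of 232 reads. Their median fold stood at the 51.5th percentile of all entries (21.6th within 5 kb), and 2 entries in the 9 kb at the other side at the 42.4th. By −log10 q the 7 entries stood at the 90.1st percentile. Their background was 53.9 to 90.2 reads, against at most 10.9 reads for the 4 other entries within 50 kb outside the gene. The values of Mnx1 given above rest on this raised background.

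**Figure D3:**
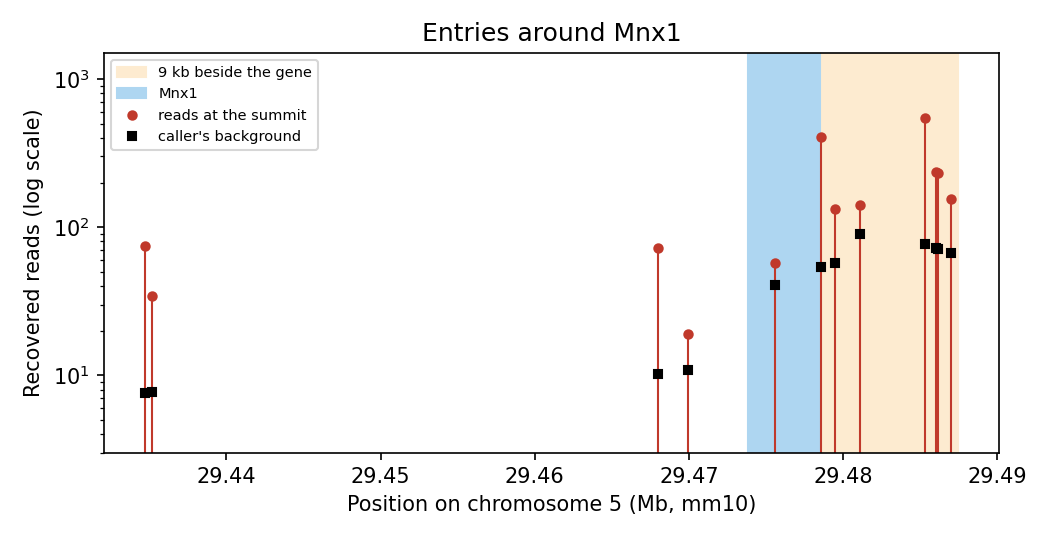
Entries within 50 kb of Mnx1 by position (horizontal axis, Mb on chromosome 5, mm10), with the recovered reads at the summit (red) and the caller's background (black) on a log axis. In the 9 kb beside the gene (shaded) the background lies between 53.9 and 90.2 reads, and outside it and the gene at 10.9 reads or less.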

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

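The share of high-background entries was tested only after the strongest entries had been seen, and the share at gene ends was predicted before. Entries outside the numbered and sex chromosomes entered no comparison. There were 502 on unplaced contigs, of which 202 lay on a single contig with a median of 358 reads. A further 36 entries lay on the mitochondrial genome, with a median of 16837 reads. They were left out because the gene table covers chromosomes 1 to 19, X and Y only. They are listed here only as signal outside the main measurement. The limit of 3 counts that a count of 0 allows does not set them apart, since every entry in the list has at least 11 reads.

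The strongest entries on the chromosomes followed a pattern of their own. Of the 100 with the highest −log10 q, 39.0% had a background of 30 reads or more, against 0.483% of all chromosomal entries. At a given fold −log10 q grows with depth, so the ranking itself draws in high-background entries. This excess alone cannot single out multi-copy sequence. Strongly accessible gene ends are argued against, since only 2.0% of these 100 lay within 1 kb of a gene end, compared with 65.7% of the entries that follow down to rank 10000. Reads of multi-copy sequence placed on few reference copies may account for the 39 with raised background, and the interval on chromosome 1 with 10129 reads is a candidate for mitochondrial reads. The other 61 had a low background and 27.9 to 55.6-fold enrichment, and their origin stays open because no sequence was used here.

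Across the chromosomes, 450 entries had 20-fold enrichment or more, with a median interval of 388 bp, and 0.67% of them lay within 1 kb of a gene end. They include a 35.7-fold entry inside Ntrk3, 164209 bp from the nearer end and so not counted among its distal entries. A 35.2-fold entry 42.5 kb from Slc5a7 is counted among the 6 of that gene.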

How the results depend on the processing

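Calls limited to q-values under 0.05 or to a background under 30 reads, comparisons over whole gene spans and random lists of named genes were added after seeing the data. No replicate could be left out and no paired analysis was possible because the list pools both replicates of 1 group. Alternatives with 1 transcription start per gene and all motif alternatives were not run, since no strand or sequence was used. Values are percentiles unless stated, and the cause of each change was not tested. The main result for gene ends kept its side of the limits in 138 of 152 values, for distal entries in 133 of 152 and for the motor neuron comparisons in 55 of 65.

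With the upper 50% of entries by −log10 q, 68925 entries were left, 28.7% of them at gene ends, and 76.9% of Hox genes had a gene-end entry. Gene-end percentiles were then 98.3 for motor neuron transcription factors and 1.28 for mature glia, now past a limit, and 92.5 for axon guidance, 82.5 for ventral interneurons, 96.2 for neural crest and 97.4 for forebrain and midbrain, no longer past it. Distal percentiles lost were 97.3 for cholinergic and 75.3 for pluripotency genes. Against motor neuron factors, ventral interneurons (94.3), endothelium (97.4) and liver (93.5) were lost and dorsal interneurons (99.7) gained. The share at gene ends was 13.6% within 500 bp, 23.0% within 2 kb, 18.8% by the middle of the peak and 20.8% for q under 0.05. A 500 bp window gave gene-end percentiles of 97.7 for motor neuron transcription factors, 97.9 for cranial motor genes and 95.3 for neural crest. Unmatched random lists gave 98.9 for motor neuron transcription factors at gene ends, and 96.6 for cholinergic, 99.8 for endothelial and 96.3 for pluripotency genes at distal sites. Over whole gene spans, liver genes reversed from 37.5 to 98.8, mesoderm rose to 99.1, endothelium to 92.5, mature glia to 91.2 and pluripotency to 93.4. Axon guidance fell to 84.5, the most it could reach there with every member holding an entry. Without high-background entries, motor neuron transcription factors stood at 86.2 at gene ends. Random lists of named genes gave 92.3 for neural crest at gene ends and 95.9 for mesoderm at distal sites.

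A reach of 50 kb gave distal percentiles of 96.2 for motor column and 98.5 for endothelial genes, and 97.45 for forebrain and midbrain against motor neuron factors. Distal sites over 5 kb away gave 94.7 for cranial motor, 85.7 for mesoderm, 98.1 for endothelium, 97.48 for liver, 79.2 for forebrain and midbrain and 98.5 for mature glia, and 98.6 for cranial motor genes against motor neuron factors. One entry per interval gave 96.5 for cholinergic, 96.5 for mesoderm and 97.8 for endothelial genes. With q under 0.05, distal values were 96.3 for mesoderm and 97.1 for pluripotency, and those against motor neuron factors 97.3 for ventral interneurons, 98.7 for dorsal interneurons and 96.6 for forebrain and midbrain. Without high-background entries that last comparison was 97.46. By −log10 q, the entries beside Mnx1 stood at 90.1 in place of 51.5. By fold they stood at 21.6 within 5 kb and 41.0 with q under 0.05. Depth limits the weakest entries, which rest on 11 reads.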

Other observations

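Tests of the Mnx1 background were chosen after its values were seen, and those of the X chromosome before, apart from the comparison over all entries. Gene families that were picked by symbol after the data were seen differed widely. Only 31 of 1110 olfactory receptor genes (2.79%) and 4 of 355 vomeronasal receptor genes (1.13%) had a gene-end entry, as did 14 of 53 keratins. By contrast, 72 of 77 ribosomal protein genes and 63 of 67 replication-dependent histone genes had one, with a median of 1 and 0 distal entries. All 19 Sox genes had a gene-end entry, as did 11 of 12 LIM homeobox, 40 of 44 forkhead, 6 of 9 Pax and 3 of 4 Nfi genes, with a median of 9, 13.5, 5.5, 20 and 20.5 distal entries. The share for Pax genes (66.7%) was near that of all genes (67.1%). The clustered protocadherins had an entry at 25 of 57 genes, genes of interleukins and their receptors at 36 of 83, the Zfp zinc finger genes at 352 of 397 and the mitochondrial ribosomal protein genes at 76 of 78.

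The caller's background beside Mnx1 may reflect extra copies of the reporter fragment. The median background in the 9 kb at its higher-coordinate side was 71.6 reads, against 8.90 for the 4 other entries within 50 kb, a ratio of 8.05. An entry inside Mnx1 was in neither group and had a background of 40.5 reads. Entries in the neighbouring 9 kb can raise that local value, so it does not show whether the excess stopped at the edge of the gene. The highest background beside Mnx1 was 2.203 times that beside Neurog2, a gene outside the naming rule and the next of 330 listed genes with entries. That background is local, and it belongs to a 1.55-fold entry lying between entries of 406 and 545 reads. Because strong neighbours can raise it and the limit was set afterwards, it cannot decide against open chromatin of the degree seen at other developmental genes. Among 102 loci with a background of 30 reads or more, Mnx1 ranked 9. No entry lay beyond the 9 kb on that side within 50 kb, so the outer boundary could not be seen, and an unusually open domain in these cells or ambiguous mapping were not tested.

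The X chromosome had 18.9 entries per Mb, against 55.3 on autosomes, where the lowest chromosome had 48.5. Lower gene density is argued against as the whole cause, since distal entries per 100 kb of gene territory were also fewer, 1.68 against 5.13, a ratio of 0.328. A dosage of 1 X per cell in some embryos was not settled. At gene ends with an entry, the median was 63 reads on X and 99 on autosomes, a ratio of 0.636 (95% bootstrap interval over genes 0.586 to 0.670). Over all entries it was 26 reads on X, within the 22 to 26 of single autosomes, and the median of 3.77-fold on X was the highest of any chromosome. These 2 medians cannot decide on dosage, because weak sites below the caller's limit, where the smallest entry has 11 reads, drop out of them. X inactivation in female embryos and fewer regulatory sites on X stay open and untested, and the labels do not give the sex of the embryos. The Y chromosome held 195 entries with a median of 36 reads, and 36 high-background entries lay in the locus of Gm52481. Whether the Y entries come from male embryos or from multi-copy sequence was not tested.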
